A study of Drosophila melanogaster with 12 samples.

How the data were processed

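Whole-body total RNA of 12 pools of 45 male Oregon R flies was profiled, each pool on 1 Affymetrix Drosophila GeneChip. Flies were injected with Drosophila C virus (DCV) or with Tris and collected after 24 or 48 h, which gives 4 groups of 3 arrays. Groups and replicate letters were taken from the sample titles. The labels call the samples biologically independent and say no more on how the flies of a pool were chosen.

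The deposited table holds 1 intensity for each of 14010 probe sets on each array, made with Affymetrix Microarray Suite 5.0 and Excel, per the labels. Those labels also speak of keeping only values flagged present, but no array had a missing value. Every array's deposited intensity was a whole multiple of 0.1 signal unit divided by 1 constant of that array, for 100% of values. The constants lay between 93.25 and 163.7. What they stand for is not given in the sources used here. With the constant undone, the 2% trimmed mean was 100.0 on each array, and the median signal was 35.7 to 38.7 on the Tris arrays and 42.8 to 47.7 on the DCV arrays. Signals below are given on this undone scale, before the normalization that the tests used, so a ratio of 2 signals differs somewhat from the fitted change. Probe set summarization and background steps are those of the authors' software and were not repeated.

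The experiment files of the instrument, deposited beside the table, hold settings and no measurement of RNA. They were used only to group the arrays into 5 fluidics runs on 2 days. Run 1 held replicate b of DCV and replicate c of Tris at 48 h, and run 2 held the 3 DCV arrays of 24 h with replicate a of DCV at 48 h. Run 3 held replicate c of DCV at 48 h, for which a communication error was logged. Run 4 held the 3 Tris arrays of 24 h, and run 5 the other 2 Tris arrays of 48 h. No DCV and Tris array of 24 h shared a run, so the arrays of 24 h alone cannot tell run from treatment. For 2 results an indirect comparison was made through run 1.

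The 2% trimmed means of the deposited values ranged from 0.611 to 1.07, more than 10% from their mean. By the rule fixed for that case, the arrays were therefore quantile normalized. Values were then floored at the 25th percentile of the table, 14.2 signal units, and log2 transformed. The 44 control probe sets were left out. Of the other 13966 probe sets, the 11959 above the floor on at least 3 of the 12 arrays were tested. A fold change with 1 group at the floor on all 3 arrays is a lower bound and is given as such. The number of arrays, 3 per group, limits the precision.

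Probe sets were named from the platform annotation, updated by gene identifier to the RefSeq annotation of the fly genome. Of the 13966 probe sets, 12443 had 1 gene symbol, 327 had several and 1196 had none, and 12394 of the first kind matched RefSeq. No gene was named from a probe set with several symbols. Coordinates were not used here.

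In all, 5 contrasts were fitted with limma 3.58.1 in R 4.3.3 as 4 group means over all 12 arrays, with a mean-variance trend and no block. They were DCV against Tris at 24 h and at 48 h, the difference between those effects, and 48 h against 24 h within Tris and within DCV. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 11959 probe sets, with a threshold of 0.05. Values are log2 fold changes with the standard error of the fit (SE). Single measures of array quality were compared with two-sided exact permutation tests, for which 3 against 3 arrays cannot give a p under 0.1. Further computations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

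A set of 29 gene lists was written from general knowledge before the data were examined, as were the samples, the tests, the other settings to try and the rule for named genes. They cover immune pathways, stress, metabolism, other cell processes, and markers of organs, of sex and of cell types that whole flies could hold. Of the 503 list entries, 361 had a probe set. Each gene was represented by the probe set with the highest mean. The 27 lists with at least 3 measured genes were tested with camera against the other genes, 9720 in all, at a preset correlation of 0.01 between genes, with adjustment over the lists. The test was repeated with an estimated correlation and with fry. The estimate was above the preset for some lists, such as glycolysis (0.22) and muscle (0.091). It was below the preset for others, such as insulin, starvation and lipid (0.00056), detoxification (-0.019) and proteasome genes (-0.012). For such lists a call lost with the estimate cannot be put down to correlation between members. The list of genes reported as induced by DCV was written from memory of the study on these same samples.

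The genes named for the DCV effect at each time are the 12 largest rises and the 12 largest falls past the threshold whose 3 DCV arrays all lay on the same side of the 3 Tris arrays. For the other contrasts the 8 largest in each direction are named where that many passed. For each list up to 4 members past the threshold with the largest changes are named, or up to 2 as values where none passed. All measured genes of the list from the study are named. Where a gene had several probe sets its value is from the brightest, even where a dimmer one met the rule, and a disagreement in direction is stated.

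The fit was tested on simulated data with 200 probe sets changed. All groups had the probe set means of Tris at 24 h and 1 common spread per probe set, and probe sets varied independently. Since 2407 probe sets were called in the data at 24 h, the shares called below need not hold there. The simulated list tests do not cover real correlation between genes. At 24 h, over about 11667 probe sets, 6.68% of those changed by 0.5 on the log2 scale were called, 28.8% of those changed by 1 and 61.6% of those changed by 2. At 48 h, over about 11662 probe sets, the shares were 6.38%, 25.8% and 59.6%. Unchanged probe sets made up 6.97% of the calls at 24 h and 5.30% at 48 h, pooled over 10 simulations. With nothing changed, the 10 simulations gave 0 calls at 24 h and 1 call at 48 h. A list of 20 genes moved by 0.5 was found in 10 of 10 simulations at each time, with 2 of 270 other list tests called at 24 h and 0 of 270 at 48 h.

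Other settings fixed beforehand covered the scaling between arrays, the floor, the filter, the variance model, the arrays in the fit, the threshold, blocks for run, day and replicate letter, each array left out in turn, and the list test. Settings chosen after seeing the data were the deposited values and a spike-in scaling, a pseudocount of 0.01, array weights, the fit without the 2 arrays of the earlier day, and run and day blocks in the list test at 48 h. With the run as a fixed block, the DCV effect at 48 h equals the difference within run 1, with 5 residual degrees of freedom. Lone arrays of a run are then assumed to vary like the others. For gene lists this contrast is 1 DCV against 1 Tris array. The list test then compares genes, so its p-values do not measure the spread between pools. Where a list still passed, only its median within run 1 is given. Viral RNA was not analysed here.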

Results

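Transcript levels were measured in whole male Oregon R flies after injection of Drosophila C virus (DCV), a positive-strand RNA virus of fruit flies, or of Tris, the buffer of the virus stock. Flies were collected 24 or 48 h after injection. Each of the 4 groups had 3 samples of 45 flies, and each sample was read on 1 oligonucleotide array. The series is about the place of the Jak-STAT pathway in the response to the virus, and these arrays show which transcripts differed between virus and buffer. Pairs of arrays of the same group correlated across probe sets at r = 0.963 to 0.967 for Tris at 24 h and 0.960 to 0.963 for Tris at 48 h. The values were 0.919 to 0.932 for DCV at 24 h and 0.944 to 0.957 for DCV at 48 h. No 2 arrays held identical values, and the highest correlation between any 2 was 0.969.

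The first principal component held 39.0% of the variance and put the groups in order. Scores were -34.4 to -26.9 on the 6 Tris arrays, 13.9 to 15.1 on the DCV arrays of 48 h and 43.6 to 50.6 on those of 24 h. The added bacterial and phage hybridization control transcripts were brighter on the DCV arrays. At 24 h their mean log2 signal was 9.72 ± 0.25 against 8.55 ± 0.22 (SD, n = 3, exact permutation p = 0.1, the smallest possible). At 48 h they were at 9.56 ± 0.19 against 8.27 ± 0.24 (SD, n = 3, exact permutation p = 0.1). These are 2.26-fold and 2.45-fold differences, and the pair of 48 h arrays that shared run 1 differed by 0.82 on the log2 scale. The log2 ratio of 3' to 5' signal, a measure of RNA integrity, differed between DCV and Tris by 0.82 for eIF-4a at 24 h (exact permutation p = 0.1) and by -0.67 for GAPDH (exact permutation p = 0.2). For actin at 24 h the difference was 0.28 (exact permutation p = 0.5). At 48 h the differences were 0.02 for eIF-4a (exact permutation p = 1.0), -0.78 for GAPDH (exact permutation p = 0.1, and -0.25 within run 1) and -0.20 for actin (exact permutation p = 0.6).

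**Figure D1:**
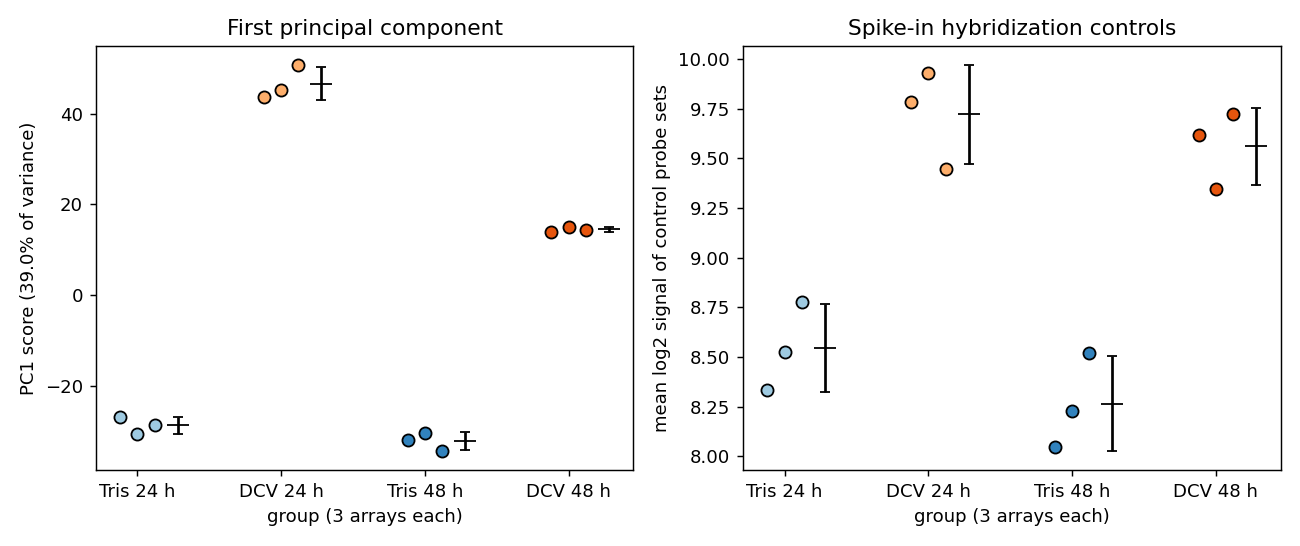
Left, score of each array on the first principal component of log2 expression, by group; right, mean log2 signal of the added control transcripts, by group. Points are arrays, dashes with bars are the mean ± SD of 3 arrays, and the DCV arrays of 24 h had scores of 43.6 to 50.6 against -34.4 to -26.9 for Tris.

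At 24 h the largest rise after DCV was that of Fst (Frost), a gene known for its induction by cold, which went from a signal of 87.6 ± 9.40 to 2524 ± 99.9 before normalization (SD, n = 3), and by 4.97 ± 0.12 on the log2 scale after it (SE, adjusted p = 1.3e-13). The attacin gene AttD rose by 4.60 ± 0.24 (adjusted p = 8.7e-10), Srg1 by 4.54 ± 0.26 (adjusted p = 2.6e-09) and the lysozyme gene LysS by 3.33 ± 0.27 (adjusted p = 1.9e-07). Jon25Biii, a serine protease of the Jonah family of digestive enzymes, had the largest fall, from a signal of 3146 ± 119 to 75.5 ± 8.17 before normalization (SD, n = 3), and -5.50 ± 0.09 on the log2 scale after it (adjusted p = 1.8e-15). Sodh1, a sorbitol dehydrogenase, changed by -4.38 ± 0.09 (adjusted p = 6.3e-14), and the serum protein gene Lsp2 by -4.31 ± 0.19 (adjusted p = 1.2e-10). In each of these genes the 3 DCV arrays lay on the same side of all 3 Tris arrays. Values given for genes from here on are log2 changes with their SE.

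Among the other largest rises were CG15043 at 3.31 ± 0.13, MFS12 at 3.35 ± 0.32 and CG4269 at 2.95 ± 0.11, and CG4741 at 4.13 ± 0.37, for which a dimmer probe set gave -0.86. The transcription factor gene Ets21C was at the floor on all 3 Tris arrays and rose by at least 3.48. Vajk2 entered by a dimmer probe set at 3.09, while its brightest gave 0.32 ± 0.34 (adjusted p = 0.58). Further falls were those of the lysosomal alpha-mannosidase genes LManV at -5.37 ± 0.24 and LManVI at -4.17 ± 0.15, of Jon25Bi at -4.75 ± 0.25 and Jon99Ci at -4.30 ± 0.12, of CG6295 at -4.48 ± 0.26 and CG8562 at -4.36 ± 0.28, and of CG11892, CG17752 and CG18180 at -4.37, -4.12 and -4.11. Of the 24 genes named for size, 23 passed by their brightest probe set, and all 23 passed without any single array.

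**Figure D2:**
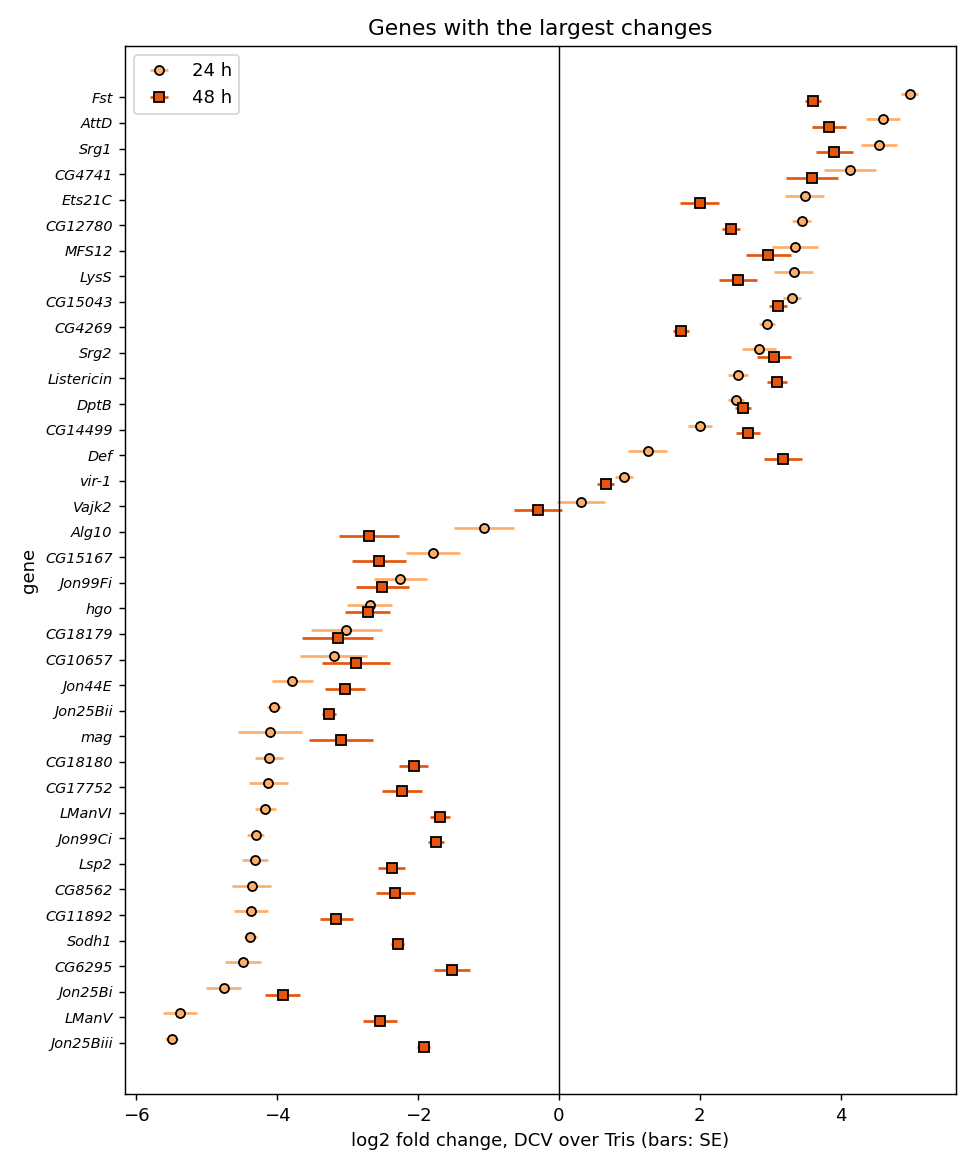
Log2 fold change of DCV over Tris, with its SE, for the genes with the largest changes. Circles are 24 h and squares 48 h, each from 3 DCV and 3 Tris arrays, and Fst stood at 4.97 and 3.61.

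By limma, 2407 of 11959 probe sets passed at 24 h, 1169 higher and 1238 lower in DCV, of which 463 and 734 changed at least 2-fold. The arrays of the groups did not overlap for 4017 probe sets (33.6%), where chance gives 10%. The split depended on the scaling between arrays: it was 1600 higher and 1124 lower with a common trimmed mean (shift of the median of all genes 0.21), 355 and 2466 with the values as deposited (shift -0.24), and 82 and 5888 when scaled to the added control transcripts (shift -0.80). The arrays of 24 h alone cannot tell run from treatment, since no DCV and Tris array shared a fluidics run. An indirect comparison through run 1 is given below for the control transcripts and the midgut markers only. With the run as a random block 2906 passed (estimated correlation -0.069, which narrows the errors).

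Genes of the antimicrobial peptides rose at 24 h, 7 of the 8 measured, with 1 lower (the same counts adjusted over the list alone), a median log2 change of 1.67 and adjusted p = 9.0e-07. DptB rose by 2.51 ± 0.12, Mtk by 2.26 ± 0.14 and CecB, at the floor on all 3 Tris arrays, by at least 2.08, while Drsl5, named only after its values were seen, fell, at -1.06. Of 5 measured genes that the study reported as induced by DCV, 4 rose (4 adjusted over the list alone; adjusted p = 2.0e-06), which is not independent evidence because the list came from these samples. They were CG12780 at 3.44 ± 0.13, Vago, a secreted antiviral factor, at 2.84 ± 0.25, Listericin, an antibacterial protein, at 2.54 ± 0.14, and vir-1 at 0.93 ± 0.12 (2.96 by a dimmer probe set, and -0.50 for the brightest on the spike-in scaling). Diedel stood at 0.28 ± 0.42 (adjusted p = 0.71). The list was written with 8 genes. Of these upd3 and TotM had no probe set, and upd2 was not above the floor on enough arrays to be tested.

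Components of the Jak-STAT pathway did not pass against the other genes by camera at 24 h (median 0.14, adjusted p = 0.47) but passed upward by fry, which tests a list by itself (adjusted p = 0.040): 1 of 10 rose, 1 fell and 8 did not pass (2 and 1 adjusted over the list alone). The receptor gene dome rose by 1.15 ± 0.21 with a dimmer probe set at -0.19, and the transcription factor gene Stat92E fell, at -0.83 ± 0.19. Of this list hop, upd3 and Socs36E had no probe set, and upd2 was too often at the floor to be tested. TotE, the 1 measured member of the Turandot stress genes, rose by 1.28 ± 0.43 (adjusted p = 0.045), a call lost when any 1 of 9 arrays was left out (adjusted p = 0.051 to 0.17). The thioester protein genes Tep3 and Tep4 were at 0.54 ± 0.33 (adjusted p = 0.29) and -0.29 ± 0.12 (adjusted p = 0.11).

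Toll pathway components went both ways, 3 of 13 up and 2 down (3 and 2 adjusted over the list alone; adjusted p = 0.61), with a median of -0.02 against a mean of 0.07 and an upward test. The NF-kappaB gene dl rose by 1.73 ± 0.24 and the ligand gene spz by 1.70 ± 0.20, and GNBP3, a recognition protein gene, fell, at -2.17 ± 0.23. In the Imd pathway 3 of 12 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.49), among them Rel, its NF-kappaB factor, at 2.27 ± 0.17, key at 1.06 ± 0.21 and the amidase gene PGRP-SC2 at -2.30 ± 0.08. Of the small RNA pathway genes 0 of 11 rose and 2 fell (0 and 2 adjusted over the list alone; median -0.14, adjusted p = 0.57). For melanization and serpin genes the counts were 1 up and 1 down of 12 (2 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.22). For hemocyte markers they were 0 up and 1 down of 12 (0 and 1 adjusted over the list alone; median -0.37, adjusted p = 0.22). In both of these lists the fall was that of PPO2, a prophenoloxidase gene, at -0.56 ± 0.12, with a dimmer probe set at 0.57, and the protease gene Sp7 of the first list rose by 1.62 ± 0.21.

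Markers of midgut digestion fell at 24 h, 20 of 29, with 2 higher (20 and 3 adjusted over the list alone), a median of -1.57 and adjusted p = 1.6e-15. Beside the Jonah proteases, the lipase gene mag fell, at -4.10 ± 0.45, while the lysozyme gene LysS rose. Of the glycolysis genes 8 of 10 fell and none rose (8 and 0 adjusted over the list alone; median -0.89, adjusted p = 2.7e-08), such as Pglym78 at -1.82 ± 0.09, Gpdh1 at -1.28 ± 0.16 and Gapdh1 at -1.13 ± 0.07. For the citrate cycle and respiratory chain 14 of 22 fell and none rose (17 and 0 adjusted over the list alone; median -0.51, adjusted p = 2.3e-10), including Idh at -1.35 ± 0.08 and the ATP synthase gene blw at -1.12 ± 0.09. The list of insulin, starvation and lipid synthesis genes fell (median -0.24, adjusted p = 0.020, but adjusted p = 0.072 with an estimated correlation), with 6 of 15 lower and 1 higher (6 and 1 adjusted over the list alone). The 3 largest were the fatty acid synthesis genes ACC at -2.41 ± 0.09, FASN1 at -2.15 ± 0.10 and Desat1 at -1.16 ± 0.18.

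Detoxification and antioxidant genes fell as a list (median -0.38, adjusted p = 0.014, but adjusted p = 0.058 with an estimated correlation), 8 of 20 lower and 4 higher (9 and 5 adjusted over the list alone). The cytochrome P450 gene Cyp6g1 stood at -2.02 ± 0.11 and the catalase gene Cat at -1.24 ± 0.09. Muscle markers fell (median -0.44, adjusted p = 0.0042, but adjusted p = 0.12 with an estimated correlation), 10 of 16 lower and 3 higher (10 and 4 adjusted over the list alone). The gene fln stood at -1.70 ± 0.15, TpnC4 at -1.37 ± 0.18 and Tm2 at -1.05 ± 0.17. Proteasome genes fell (median -0.22, adjusted p = 0.048, but adjusted p = 0.10 with an estimated correlation), 7 of 21 lower and 1 higher (7 and 2 adjusted over the list alone). Prosalpha6 stood at -0.94 ± 0.19 and Prosalpha4 at -0.85 ± 0.20. The call of the proteasome list was lost without replicate b or c of Tris (adjusted p = 0.079 and 0.060) or replicate b of DCV (adjusted p = 0.15). Under the 4 other scalings each of the 7 lists that fell as a whole at 24 h also passed downward by camera (adjusted p at most 0.0014). Their medians were -0.36 to -1.91 relative to the median of all genes. Apart from the floor, the 4 scalings differ from one another only by 1 factor per array. Here and below they are therefore not 4 separate checks of a list set against the other genes.

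Heat shock genes rose as a list (median 0.13, adjusted p = 0.014, but adjusted p = 0.12 with an estimated correlation and 0.13 to 0.98 under the 4 other scalings), 3 of 9 higher (3 adjusted over the list alone), and the median was -0.23 as deposited and -0.86 on the spike-in scaling. The chaperone genes l(2)efl and stv rose by 1.64 ± 0.09 and 1.38 ± 0.15. Testis markers rose, 10 of 18 (10 adjusted over the list alone; median 0.48, adjusted p = 8.6e-06), but their median was -0.12 as deposited and -0.75 on the spike-in scaling (adjusted p = 0.27 and 0.82). Mst84Db rose by 0.75 ± 0.09 and Mst84Dd by 0.61 ± 0.06, and on the spike-in scaling they stood at -0.20 and -0.41. Of the ribosomal protein genes 4 of 12 rose (5 adjusted over the list alone; median 0.05, adjusted p = 0.14), and the median was -0.12 with median centring, -0.52 as deposited and -1.15 on the spike-in scaling.

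The remaining lists did not pass by camera at 24 h with the quantile normalized values. By fry the fat body, Malpighian tubule, protein folding and hemocyte lists passed downward (adjusted p = 2.3e-06, 2.2e-05, 2.2e-04 and 2.4e-04), and the melanization and ribosomal protein lists upward (adjusted p = 0.0018 and 0.0022). By camera under all 4 other scalings the Malpighian tubule, fat body and protein folding lists passed downward (adjusted p = 0.0019 to 0.0045, 0.019 to 0.032 and 0.020 to 0.037). Under 3 of them, not the trimmed mean, accessory gland markers passed downward (adjusted p = 0.0022 to 0.049), and female markers passed upward as deposited and on the spike-in scaling (adjusted p = 0.032 and 0.0045). Upward here is relative to the other genes, and the median of all genes was -0.24 as deposited and -0.80 on the spike-in scaling. Fat body markers went both ways, 3 up and 4 down of 8 (3 and 4 adjusted over the list alone; median -0.24, adjusted p = 0.088). The odorant-binding protein gene Obp99b stood at 2.49 ± 0.14 and the lipoprotein gene apolpp at -2.24 ± 0.12. Accessory gland markers numbered 4 up and 5 down of 13 (4 and 6 adjusted over the list alone; median -0.25, adjusted p = 0.47). Acp76A stood at -1.61 ± 0.31. Malpighian tubule markers numbered 1 up and 3 down of 8 (1 and 4 adjusted over the list alone; median -0.79, adjusted p = 0.057). Alp4 stood at -1.27 ± 0.17 and salt at -0.95 ± 0.19. In the apoptosis list 3 of 8 rose and 2 fell (3 and 2 adjusted over the list alone; median 0.33, adjusted p = 0.50). The caspase gene Dronc stood at 1.70 ± 0.32 and Buffy at -1.29 ± 0.30. Circadian genes numbered 1 up and 2 down of 9 (2 and 2 adjusted over the list alone; median -0.17, mean 0.05, test downward, adjusted p = 0.93). The gene vri stood at 1.78 ± 0.23 and tim at -0.89 ± 0.19. Protein folding genes of the endoplasmic reticulum numbered 4 down of 9 (1 up and 4 down adjusted over the list alone; median -0.05, adjusted p = 0.18). Gp93 stood at -0.91 ± 0.11. Autophagy genes numbered 2 up and 1 down of 14 (2 and 1 adjusted over the list alone; median 0.27, adjusted p = 0.47). Atg13 stood at -0.70 ± 0.13. Female markers numbered 2 up and 1 down of 15 (2 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.33), and eye and nerve markers 2 up of 8 (2 adjusted over the list alone; median -0.05, mean 0.02, adjusted p = 0.47). The arrestin gene Arr2 stood at 0.79 ± 0.07, and at -0.53 on the spike-in scaling.

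**Figure D3:**
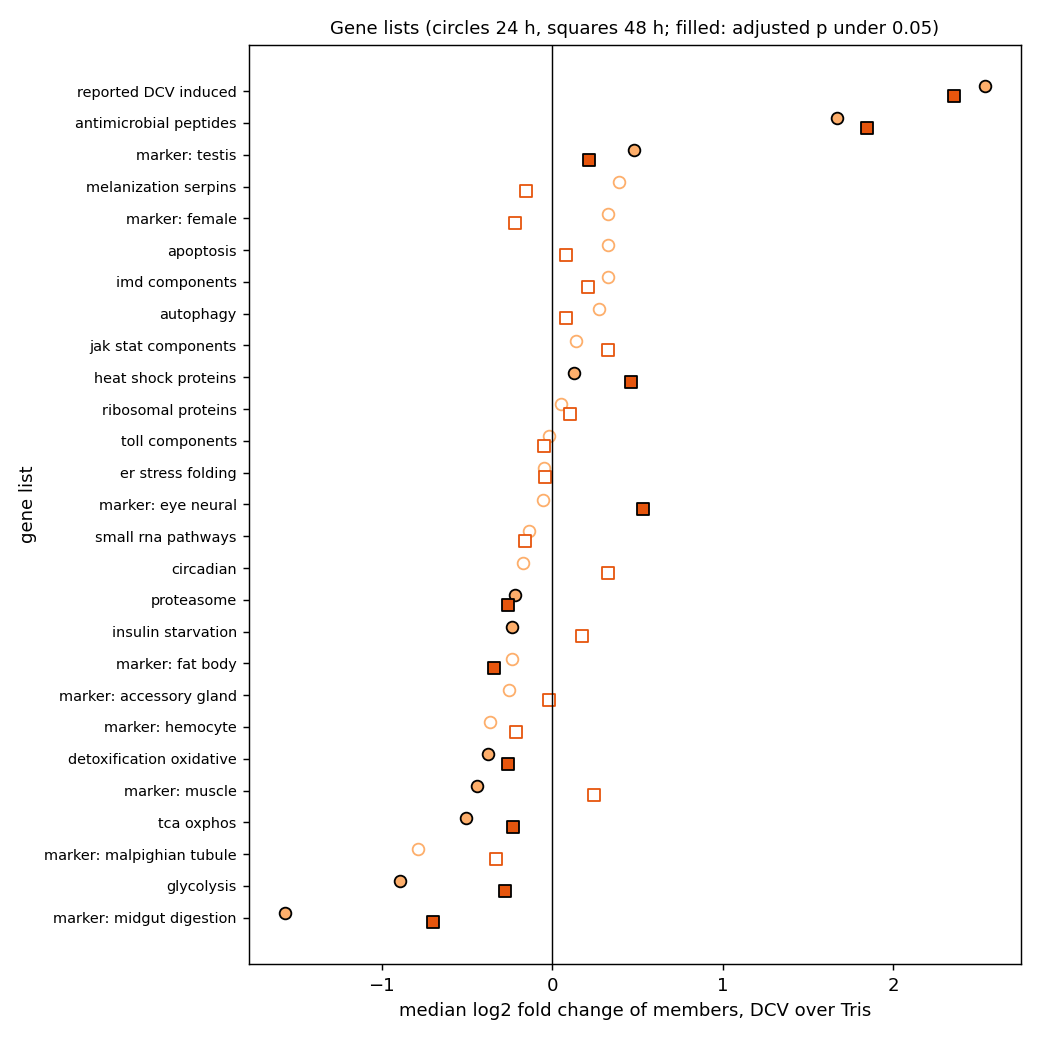
Median log2 fold change of DCV over Tris for each gene list, circles at 24 h and squares at 48 h, filled where the list test gave an adjusted p under 0.05. Midgut digestion markers stood at -1.57 and -0.70 and antimicrobial peptide genes at 1.67 and 1.85, while the medians of several lists, such as heat shock and testis, lay below 0 on the spike-in scaling at both times.

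At 48 h, Srg1 rose by 3.91 ± 0.26 (adjusted p = 5.8e-08), Fst by 3.61 ± 0.12 (adjusted p = 1.8e-11) and the defensin gene Def by 3.18 ± 0.27 (adjusted p = 9.0e-07; SE, n = 3 per group). AttD, at the floor on all 3 Tris arrays, rose by at least 3.83 (adjusted p = 3.4e-08). Listericin rose by 3.10 ± 0.14, from a signal of 80.7 to 686 ± 61.1 before normalization (SD, n = 3). The largest falls were those of Jon25Bi at -3.92 ± 0.25 (adjusted p = 3.7e-08) and Jon25Bii at -3.26 ± 0.10 (adjusted p = 1.8e-11), and Jon25Biii went from 3864 ± 99.7 to 983 ± 36.4 before normalization (SD, n = 3).

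Other large rises at 48 h were those of CG15043 at 3.10 ± 0.13, Srg2 at 3.05 ± 0.24, MFS12 at 2.97 ± 0.32, CG14499 at 2.68 ± 0.17 and DptB at 2.61 ± 0.12, of CG4741 at 3.59 ± 0.37 (-0.08 by a dimmer probe set) and of vir-1 at 0.66 ± 0.12 (2.95 by a dimmer probe set, and -0.74 for the brightest on the spike-in scaling). The other large falls were those of CG11892 at -3.16 ± 0.24, CG18179 at -3.14 ± 0.50, mag at -3.09 ± 0.45, Jon44E at -3.04 ± 0.29, CG10657 at -2.88 ± 0.48, hgo, an enzyme of tyrosine breakdown, at -2.71 ± 0.32, Alg10 at -2.70 ± 0.43, LManV at -2.54 ± 0.24 and Jon99Fi at -2.50 ± 0.37. CG15167 was at the floor on all 3 DCV arrays and fell by at least 2.55. All 24 genes named for size passed without any single array, 17 of them with the run block described next, and in each the 3 DCV arrays lay on the same side of all 3 Tris arrays.

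By limma, 1295 probe sets passed at 48 h, 627 higher and 668 lower, of which 223 and 327 changed at least 2-fold, and the arrays did not overlap for 3298 (27.6%, where chance gives 10%). The split was 282 higher and 1026 lower with the values as deposited and 48 and 7727 on the spike-in scaling (shift of the median of all genes -1.04, and 0.13 with a common trimmed mean). With the fluidics run as a block, which leaves the 1 pair of run 1, 256 probe sets passed, 113 higher and 143 lower, with a median SE of 0.47 in place of 0.28. Of 857 probe sets called without that pair, 826 (96.4%) went the same way within it. Of 89 named genes past the threshold 44 passed with the run block, including Fst at 3.35 (adjusted p = 8.3e-05), Listericin at 2.77 (adjusted p = 5.4e-04), Def at 2.74 (adjusted p = 0.024) and Jon25Bi at -3.80 (adjusted p = 0.0038). Of the 24 named for size 7 were lost. The rises were MFS12 at 2.88 (adjusted p = 0.052) and, by its brightest probe set, vir-1 at 0.54 (adjusted p = 0.37). For the dimmer probe set of vir-1, by which it was among the largest rises, no value with the run block is given here. The falls were mag at -2.09 (adjusted p = 0.20), CG10657 at -3.41 (adjusted p = 0.060), Alg10 at -2.45 (adjusted p = 0.23), CG15167 at -2.56 (adjusted p = 0.16) and Jon99Fi at -1.57 (adjusted p = 0.21). Others lost among those given below were dome at 1.37 in place of 1.22 (adjusted p = 0.13), Pglym78 at -0.71 in place of -0.68 (adjusted p = 0.088), Prosbeta5 at -0.67 in place of -0.70 (adjusted p = 0.41) and trp at 0.26 in place of 0.65 (adjusted p = 0.72). So were Mst84Db at 0.56 in place of 0.45 (adjusted p = 0.14), InR at 1.43 in place of 1.57 (adjusted p = 0.39), fln at -0.68 in place of -0.83 (adjusted p = 0.29) and Mlp84B at 0.58 in place of 0.62 (adjusted p = 0.12). Of these 15, Jon99Fi and trp shrank by over 1.5 times (-2.50, 0.65 without the block). The other 13 stayed within 1.5 times, under the wider SE.

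Antimicrobial peptide genes rose at 48 h, 7 of 8 and none lower (7 and 0 adjusted over the list alone; median 1.85, adjusted p = 4.3e-13). Their median within run 1 was 1.92. Of the 5 genes from the study's own list 4 rose (4 adjusted over the list alone, and adjusted p = 2.3e-08 by camera, with a median of 2.08 within run 1), again not independent evidence. They included CG12780 at 2.44 ± 0.13 and Vago at 2.36 ± 0.25, and Diedel stood at 0.38 ± 0.42 (adjusted p = 0.68). Jak-STAT components numbered 2 up of 10 (2 adjusted over the list alone; median 0.33, adjusted p = 0.065). The gene dome stood at 1.22 ± 0.21, with a dimmer probe set at 0.16. The list passed upward under 3 other scalings, not the trimmed mean (adjusted p = 0.019 to 0.046, with a median of -0.32 on the spike-in scaling), and without replicate c of Tris (adjusted p = 0.036), and its median within run 1 was 0.04. TotE stood at 0.54 ± 0.43 (adjusted p = 0.53), Tep3 at 0.77 ± 0.33 (adjusted p = 0.17) and Tep4 at -0.02 ± 0.12.

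Toll components numbered 3 up and 1 down of 13 (3 and 1 adjusted over the list alone; median -0.05, mean 0.13, test upward, adjusted p = 0.55). The gene dl stood at 1.86 ± 0.24 and spz at 1.74 ± 0.20. Imd components numbered 1 up and 1 down of 12 (2 and 1 adjusted over the list alone; median 0.21, adjusted p = 0.53). Rel stood at 1.72 ± 0.17 and PGRP-SC2 at -1.02 ± 0.08. None of the 11 small RNA genes passed (0 adjusted over the list alone; median -0.16, adjusted p = 0.42). The gene loqs stood at -0.41 ± 0.13 and Tudor-SN at -0.85 ± 0.31. Melanization genes numbered 1 up of 12 (1 adjusted over the list alone; median -0.16, mean 0.03, adjusted p = 0.996), and hemocyte markers 1 up of 12 (1 adjusted over the list alone; median -0.21, adjusted p = 0.92).

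Midgut digestion markers fell at 48 h, 16 of 29 with 1 higher (17 and 1 adjusted over the list alone; median -0.70, adjusted p = 1.7e-14). Within run 1 their median was -0.80. Citrate cycle and respiratory chain genes fell, 5 of 22 (10 lower and 1 higher adjusted over the list alone; median -0.23, adjusted p = 3.6e-04). Idh stood at -0.83 ± 0.08 and COX4 at -0.48 ± 0.07. Glycolysis genes fell, 3 of 10 (4 adjusted over the list alone; median -0.28, adjusted p = 0.0055, but adjusted p = 0.20 with an estimated correlation). Pglym78 stood at -0.68 ± 0.09 and Gapdh1 at -0.62 ± 0.07. Proteasome genes fell, 6 of 21 (7 lower and 1 higher adjusted over the list alone; median -0.26, adjusted p = 0.0045). Prosalpha4 stood at -0.98 ± 0.20 and Prosbeta5 at -0.70 ± 0.16. Within run 1, which holds 1 DCV and 1 Tris array of 48 h, the medians of these 3 lists were -0.24, -0.31 and -0.18.

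Detoxification genes fell, 6 of 20 lower and 2 higher (8 and 4 adjusted over the list alone; median -0.26, adjusted p = 0.028, but adjusted p = 0.091 with an estimated correlation). Cyp6g1 stood at -1.06 ± 0.11 and Cat at -1.01 ± 0.09. Fat body markers fell, 4 of 8 lower and 1 higher (4 and 2 adjusted over the list alone; median -0.34, adjusted p = 0.035, but adjusted p = 0.20 with an estimated correlation). Lsp2 stood at -2.37 ± 0.19, Sodh1 at -2.29 ± 0.09 and Obp99b at 1.71 ± 0.14. Both calls were lost without replicate a of Tris (adjusted p = 0.055 and 0.054) and under the run block (adjusted p = 0.10 and 0.13, with medians of -0.30 and -0.25 within run 1). Eye and nerve markers rose, 2 of 8 (4 adjusted over the list alone; median 0.54, adjusted p = 0.0045, but adjusted p = 0.11 with an estimated correlation), among them trp at 0.65 ± 0.14 and Arr2 at 0.61 ± 0.07. Their median was 0.25 within run 1 (adjusted p = 0.13 under the run block) and -0.72 on the spike-in scaling (adjusted p = 0.69, and 0.098 as deposited), where trp and Arr2 stood at -0.67 and -0.72.

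Heat shock genes rose, 3 of 9 (4 adjusted over the list alone; median 0.46, adjusted p = 0.0045, but adjusted p = 0.11 with an estimated correlation), with stv at 1.29 ± 0.15 and l(2)efl at 1.28 ± 0.09, and the list's median was -0.83 on the spike-in scaling. Testis markers rose, 5 of 18 (5 adjusted over the list alone; median 0.22, adjusted p = 2.8e-04). Mst84Db stood at 0.45 ± 0.09, and the list's median was -0.99 on the spike-in scaling. Within run 1 the medians were 0.52 and 0.24. Both calls were lost with median centring, as deposited and on the spike-in scaling (adjusted p = 0.052 to 0.99 and 0.055 to 0.33). Insulin, starvation and lipid genes went both ways, 4 up and 4 down of 15 (4 and 5 adjusted over the list alone; median 0.18, mean 0.04, test downward, adjusted p = 0.82). The insulin receptor gene InR, at the floor on all 3 Tris arrays, rose by at least 1.57, and ACC stood at -1.37 ± 0.09. Muscle markers also went both ways, 4 up and 4 down of 16 (6 and 4 adjusted over the list alone; median 0.24, adjusted p = 0.21). The gene fln stood at -0.83 ± 0.15 and Mlp84B at 0.62 ± 0.09, the second at -0.84 on the spike-in scaling.

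The other lists did not pass by camera at 48 h with the quantile normalized values. By fry the Malpighian tubule and protein folding lists passed downward (adjusted p = 6.7e-05 and 0.0051), and the Jak-STAT, Toll, circadian and ribosomal protein lists upward (adjusted p = 0.0051, 0.021, 0.021 and 0.046). By camera, Malpighian tubule and protein folding genes passed downward under all 4 other scalings (adjusted p = 0.0021 to 0.0079 and 0.030 to 0.039). Muscle, accessory gland and ribosomal protein genes passed downward on the spike-in scaling (adjusted p = 0.00051, 0.0035 and 0.0061). Circadian genes numbered 3 up of 9 (3 up and 2 down adjusted over the list alone; median 0.33, adjusted p = 0.21). The gene vri stood at 1.76 ± 0.23. Malpighian tubule markers numbered 3 down of 8 (3 adjusted over the list alone; median -0.33, adjusted p = 0.065). Alp4 stood at -1.53 ± 0.17 and salt at -1.17 ± 0.19. The counts were 3 up and 1 down of 13 accessory gland markers (3 and 3 adjusted over the list alone; median -0.02, test upward, adjusted p = 0.92), 1 up and 2 down of 9 protein folding genes (1 and 3 adjusted over the list alone; median -0.04, adjusted p = 0.23) and 1 up and 1 down of 14 autophagy genes (1 and 1 adjusted over the list alone; median 0.08, adjusted p = 0.78). Of the ribosomal protein genes 1 of 12 rose (1 adjusted over the list alone; median 0.10, adjusted p = 0.25), RpL23 at 0.35 ± 0.07, and this median was -0.11 as deposited and -1.14 on the spike-in scaling. None of the 8 apoptosis genes (0 adjusted over the list alone; median 0.08, mean -0.01, adjusted p = 0.996) or of the 15 female markers (0 adjusted over the list alone; median -0.22, adjusted p = 0.82) passed.

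The log2 changes at 24 h and 48 h came from separate arrays, and the calls shared many probe sets. These were 449 higher at both times, where 61.3 would overlap if the calls were independent, and 537 lower, where 69.2 would. Both calls use the same estimate of the spread of a probe set, so they are not independent even without a shared effect. The 2 effects went opposite ways in 4 probe sets called at both. Across the 2712 probe sets called at either time the log2 changes correlated at r = 0.82, and at r = 0.65 across all tested probe sets (probe sets are not independent replicates). Of the 990 called at both times 758 (76.6%) had the smaller change at 48 h, and the median ratio of the 48 h to the 24 h log2 change was 0.76.

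The difference between the effects was tested directly, and Jon25Biii had the largest, 3.58 ± 0.13 higher at 48 h (SE, n = 3 per group, adjusted p = 1.9e-10), having changed by -5.50 at 24 h and -1.92 at 48 h. CG6295, LManV and Jon99Ci followed the same course, with differences of 2.96 ± 0.36, 2.84 ± 0.34 and 2.56 ± 0.16, as did CG13607 at 2.71 ± 0.53. Argk1, the arginine kinase gene, had a difference of 0.89 ± 0.12 (3.35 by a dimmer probe set). Fst fell back, with a difference of -1.37 ± 0.16 (adjusted p = 1.4e-04), as did CG4269 at -1.21 ± 0.16, Mec2 at -1.25 ± 0.25 and Ag5r at -1.44 ± 0.16. The calls of LUBEL at 2.68 (at the floor on all 3 DCV arrays of 24 h), CG14762 at 2.55, CG15212 at -2.11, mei-41 at -2.0, CG18536 at -1.73 and Mdr50 at -1.69 were each lost in at least 4 of the 12 fits that left out 1 array (adjusted p = 0.050 to 0.12).

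By limma, 279 probe sets differed in effect between the times, 236 upward and 43 downward, and 268 of them moved against the direction of the effect at 24 h, which is part of the difference. The split was 317 upward and 4 downward with the values as deposited (shift of the median of all genes 0.19), and on the spike-in scaling 33 passed (shift -0.17). As lists, glycolysis genes (median 0.54, adjusted p = 4.1e-10; 4 of 10 up, 8 adjusted over the list alone), citrate cycle and respiratory genes (median 0.24, adjusted p = 4.1e-09; 5 of 22 up, 9 adjusted over the list alone) and midgut markers (median 0.55, adjusted p = 1.6e-12; 12 of 29 up and 1 down, 14 and 1 adjusted over the list alone) were less reduced at 48 h. Upward shifts were also found for muscle markers (median 0.60, adjusted p = 4.4e-09; 7 of 16 up, 9 up and 1 down adjusted over the list alone) and for insulin, starvation and lipid genes (median 0.43, adjusted p = 1.4e-05; 3 of 15 up, 5 adjusted over the list alone). These 5 kept their upward direction and call under all 4 other scalings, which differ from one another only by 1 factor per array, apart from the floor. Fat body markers passed too (median 0.27, adjusted p = 0.013, but adjusted p = 0.18 with an estimated correlation; 4 of 8 up and 2 down, as adjusted over the list alone), and testis markers went downward (median -0.18, adjusted p = 0.011, but adjusted p = 0.097 with an estimated correlation; 0 of 18 passing, 0 adjusted over the list alone), with a median of 0.04 as deposited and no call under 3 other scalings (adjusted p = 0.084 to 0.60) or by fry (adjusted p = 0.064). Fry also called detoxification, melanization and hemocyte lists (adjusted p = 0.0024, 0.021 and 0.012). By camera antimicrobial peptide genes passed upward under the same 3 scalings (adjusted p = 0.016 to 0.045), detoxification genes with median centring and as deposited (adjusted p = 0.044 and 0.0045). Accessory gland, eye and nerve, and ribosomal protein genes passed upward and female markers downward as deposited alone (adjusted p = 0.032, 0.049, 0.016 and 0.016).

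**Figure D4:**
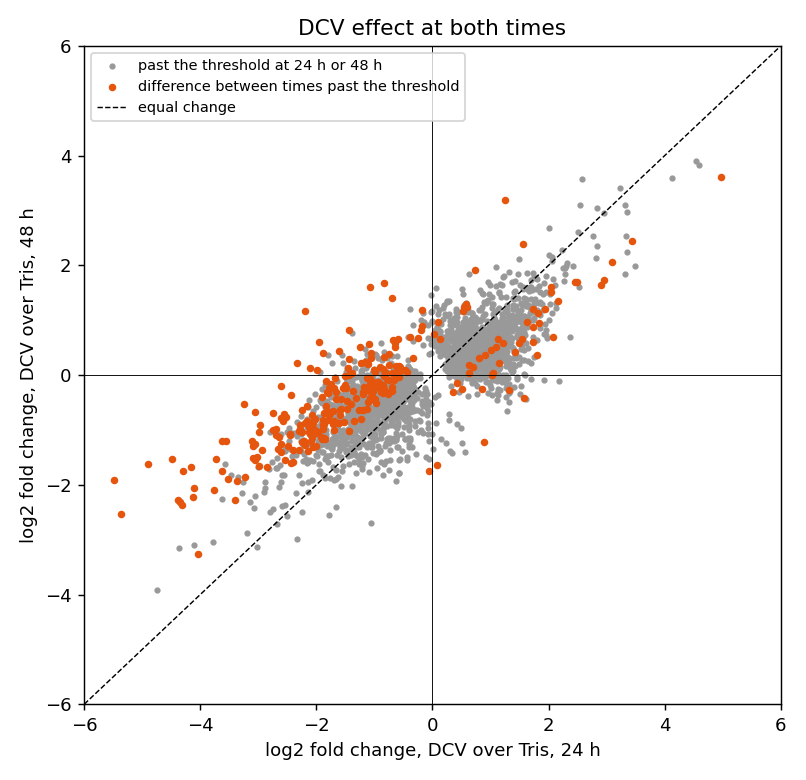
Log2 fold change of DCV over Tris at 48 h against that at 24 h for the probe sets past the threshold at either time, each point 1 probe set. Points in orange differed between the times by the test of the difference (279 probe sets), and the dashed line marks equal changes.

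Between 24 and 48 h after Tris alone, TpnC4, a troponin C gene, rose by 1.22 ± 0.18 (SE, n = 3 per group, adjusted p = 0.012), CG18609 by 1.10 ± 0.14 (adjusted p = 0.0079), the vitamin transporter gene Smvt by 1.15 ± 0.16 and the respiratory chain gene UQCR-14 by 1.03 ± 0.15. Def fell, at -1.83 ± 0.27 (adjusted p = 0.012), as did Arc1 at -1.25 ± 0.20, the transcription factor gene hry at -0.64 ± 0.09 and Prps at -0.70 ± 0.13. Smaller rises were those of Ag5r, msopa, CG14125 and Obp56g, at 0.67, 0.61, 0.59 and 0.50. By limma 15 probe sets passed, 9 up and 6 down, against 784 before adjustment at the same threshold. The split was 9 up and 12 down with median centring and 10 and 2 on the spike-in scaling (shift of the median of all genes 0.26), and 41 passed with the fluidics run as a random block. Only 1 probe set passed without replicate a of Tris at 24 h and 1 without replicate b, 2 passed without replicate c and 8 without replicate a at 48 h, and each of the 12 genes named lost its call without at least 2 single arrays.

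In flies with DCV, the rises from 24 to 48 h were led by Jon25Biii at 3.94 ± 0.09 (SE, n = 3 per group, adjusted p = 2.6e-13), CG6295 at 2.98 ± 0.26, LManV at 2.91 ± 0.24 (-0.07 by a dimmer probe set), CG9458 at 2.66 ± 0.32, Jon99Ci at 2.53 ± 0.12, LManVI at 2.51 ± 0.15, CG12990 at 2.49 ± 0.14 and CG14630 at 2.36 ± 0.21. The falls were led by CG4860 at -2.04 ± 0.41 (adjusted p = 0.0042), Cpr64Aa at -1.89 ± 0.51, nab at -1.78 ± 0.37, dany at -1.77 ± 0.38, CG7720 at -1.66 ± 0.45, CG10337 at -1.66 ± 0.40, CG13217 at -1.66 ± 0.43 and hwt at -1.65 ± 0.34. By limma 902 probe sets passed, 582 up and 320 down, against 739 and 40 with the values as deposited (shift of the median of all genes 0.13) and 369 and 10 on the spike-in scaling. With the fluidics run as a block, which leaves replicate a of 48 h against the 3 arrays of 24 h, 277 passed, 219 up and 58 down. All 8 named rises passed (Jon25Biii at 3.98, CG6295 at 3.21), and of the named falls CG7720 did (-2.14, adjusted p = 0.012), while the 7 others did not (adjusted p = 0.16 to 0.56). These were CG4860 -2.11, Cpr64Aa -2.23, nab -1.84, CG13217 -1.66, hwt -1.65, dany -1.0 and CG10337 -0.67, of which dany and CG10337 shrank by over 1.5 times. Without single arrays the calls of CG7720, CG10337, CG13217 and Cpr64Aa were lost (adjusted p = 0.052 to 0.15).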

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

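The test of the difference, the list tests, the counts over splits of the unaltered values and 2 of the 4 other scalings were planned. The splits with the mean DCV effect removed and the tests of fluidics run, scaling, RNA quality, bright genes and midgut share were chosen only after the result was seen. With the arrays of each time split in other ways into DCV and Tris, 1 of 100 splits, the real one, gave as many differences between the effects as the real 279, and the highest of the others gave 146. These splits carry the DCV effect itself and are no reference for equal effects. The mean DCV effect of the 2 times was then removed from each probe set. Of 100 drawn splits 1, the real one, gave as many as the real 283, and the highest of the others gave 1. This argues against chance for the count only as far as arrays can be exchanged within each time. At 24 h the median SD was 0.33 for DCV and 0.20 for Tris. The other splits also still hold the difference between the times in their spread, which lowers their counts. For the DCV effect the 10 splits at each time are too few for a share under 0.05: the real counts were 2407 and 1295, 1 of 10 splits each, and the highest others 0 and 0. The same holds for 48 h against 24 h within Tris (15, highest other 1), within DCV (902, highest other 4) and for the lists at 24 h (11, highest other 5) and 48 h (11, highest other 4).

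The effect of DCV differed between 24 and 48 h by a test of the difference itself in 279 probe sets, 7 gene lists and the genes below. List medians of the difference were 0.43 for insulin, starvation and lipid genes, 0.54 for glycolysis, 0.24 for the citrate cycle and respiratory chain, 0.55 for midgut digestion, 0.60 for muscle, 0.27 for fat body and -0.18 for testis. The last 2 lost the call with an estimated correlation (adjusted p = 0.18 and adjusted p = 0.097), and 0 of 18 testis markers passed.

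Over all probe sets the effect at 48 h had a slope of 0.64 (SD 0.022 over 3 choices of arrays) on that at 24 h, fitted so that the same 24 h array never entered both sides, and of at most 0.73 (SD 0.040) under 4 other scalings. A factor per array leaves this slope unchanged apart from the floor, so the 4 other scalings could not have given 1 and test nothing further. Since equal effects would give 1, the slope argues only against a factor per array as the whole cause. A distortion that depends on the signal level was not tested. The 3 choices share all arrays of 48 h, so the SD leaves out the spread of those arrays. A fluidics run as the whole cause is argued against by run 2, which held DCV arrays of both times: over all probe sets the difference within the run had a slope of 0.93 (SD 0.072) on the difference between the effects, fitted with separate arrays, where a run as the whole cause would give 0, and a part played by the runs stays open. Poorer RNA in DCV at 24 h stays open too, since the log2 ratio of 3' to 5' signal differed by 0.82 for eIF-4a, 0.28 for actin and -0.67 (SD 0.54) for GAPDH. A response of the flies that lessens with time may be present beside these, as an untested hypothesis.

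Genes less reduced or more raised at 48 h were, in log2 difference, Jon25Biii 3.58, CG6295 2.96, LManV 2.84, CG13607 2.71, LUBEL 2.68, Jon99Ci 2.56, CG14762 2.55, LManVI 2.48, CG12990 2.42, CG9458 2.42, CG14630 2.36, Sodh1 2.09, CG18180 2.05, CG8562 2.04, Lsp2 1.94, Def 1.93, CG17752 1.90, apolpp 1.60, FASN1 1.59, Tm2 1.45, Desat1 1.39, Arc1 1.38, GNBP3 1.32, PGRP-SC2 1.28, Pglym78 1.14, Cyp6a2 1.08, ACC 1.04, Vha16-1 1.04, Prps 0.97, Cyp6g1 0.96, CG18609 0.95, Argk1 0.89, fln 0.86, blw 0.85, Jon25Bii 0.78, ATPsyngamma 0.73, RFeSP 0.57, Idh 0.52 and Gapdh1 0.52. In Def, Arc1, Prps and Vha16-1 the change from 24 to 48 h was larger in Tris (-1.83, -1.25, -0.70, -0.69) than in DCV (0.10, 0.13, 0.27, 0.36). Those with a negative difference were Obp99b -0.79, CG12780 -1.0, CG4269 -1.21, Mec2 -1.25, Fst -1.37, Ag5r -1.44, Mdr50 -1.69, CG18536 -1.73, mei-41 -2.0 and CG15212 -2.11.

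Signal in probe sets outside the fly genes also differed: the added control transcripts were brighter on the DCV arrays by 1.18 at 24 h and 1.29 at 48 h on the log2 scale. Within run 1 the DCV array was above the Tris array by 0.82, against an SD of 0.32 between arrays of 1 group and run, which argues against the run as the whole cause at 48 h. At 24 h no pair shared a run, but run 2 lay above run 4 by 0.25 (SD 0.41) when each was set against run 1 within 1 treatment (-0.20 against all 48 h arrays), which argues by a narrow margin against the run as the whole cause if Tris did not change with time. A few very bright genes are argued against: the share of signal held by the 2% brightest probe sets differed by -0.52 percentage points at 24 h and 1.01 at 48 h, where 31.2 and 33.6 points would be needed. These are hybridization controls and do not measure the RNA content of the flies. Less labelled fly RNA on the DCV arrays, or RNA that the array does not read such as that of the virus, may remain as an untested hypothesis.

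The third pattern was the fall of midgut digestion markers, whose median within run 1 was -0.80 at 48 h, against an SD of 0.014 between arrays of 1 group and run, which argues against the run as the whole cause, and a part stays open. At 24 h, where the list's median was -1.57, the difference of run 2 from run 4 taken in the same way was 0.054 (SD 0.017, and 0.11 against all 48 h arrays). This argues against it too if Tris changed little with time. Within Tris the list was higher at 48 h by a median of 0.06 (camera, adjusted p = 6.9e-04), which is small beside -1.57. Relative to the median of all genes, the list stood at -1.62 at 24 h and -0.71 at 48 h with the quantile normalized values. Under the 4 other scalings the values nearest to 0 were -1.79 and -0.79. Those scalings use 1 factor per array, which cancels in this difference apart from the floor, so they cannot test the scaling as the cause. An equal loss of midgut RNA would lower all members alike, but the spread of their changes was 15 times their median SE at 24 h, with 2 members higher. At 48 h it was 10.2 times, with 1 higher. This speaks only to an equal loss, and a loss of midgut RNA that differs between members stays open. Reduced feeding or a change in gut cells may contribute, as an untested hypothesis.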

How the results depend on the processing

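Deposited values, spike-in scaling, array weights, a pseudocount of 0.01, the fit without the 2 arrays of the earlier day, and run and day blocks in the list test at 48 h were chosen after seeing the data; the other alternatives were planned. Of 7597 values for 255 named-gene results under alternatives, 6659 kept direction and side of the threshold, 838 lost the call, 27 gained one and 73 reversed, and of the list values 595, 27, 37 and 43 did. Of the named-gene reversals 51 came from the spike-in scaling, 11 from the deposited values, 3 from median centring, 1 from the trimmed mean, 2 from the run block and 5 from single arrays left out. A fixed run block could not be fitted for the effect at 24 h, the difference between times and Tris alone, and a fit of only the 2 groups compared does not apply to the difference. Probe sets near the floor of 14.2 signal units limit what low transcripts can show.

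The DCV effect at 24 h gave 2407 calls, with 1516 at an adjusted p of 0.01, 1197 with a fold of at least 2 and 5970 on the spike-in scaling, and 1816 to 2442 without single arrays. At 48 h it gave 1295, with 805 at the stricter threshold, 550 with the fold, 7775 on the spike-in scaling, 256 with the run block and 857 without the arrays of the earlier day, and 1001 to 1413 without single arrays. The difference between times gave 279, with 142, 153 and 33 in that order, 98 without a mean-variance trend, 175 without the earlier day, and 192 to 317 without single arrays. Tris alone gave 15 in the main fit by limma (784 before adjustment at the same threshold), with 2 at the stricter threshold and 6 with the fold. It gave 28 with a pseudocount of 1, 28 with a floor at the 50th percentile and 33 among the probe sets above the median of mean signal. The count was 0 without the trend, 0 with only the 2 groups, 41 with a random run block, 7 as deposited and 84 with array weights. It was 2 without the earlier day, and 1 to 18 without single arrays. DCV alone gave 902, with 511, 320 and 379 in the first order, 573 without the trend, 459 with only the 2 groups, 277 with the run block, and 687 to 917 without single arrays. Lists passing were 11 at each time, with 6 at both under an estimated correlation, 18 and 17 by fry, which asks whether a list moves by itself, and 10 to 11 and 9 to 12 without single arrays. The stricter thresholds and smaller sets follow from their construction, and for the other shifts the cause was not tested.

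Reversed at 24 h with the trimmed mean was Arr1 (-0.015), and with median centring Arr1 (-0.16) and Vha26 (-0.11). As deposited these were Hsp60A -0.23, Atg9 -0.045, Atg8b -0.045, janB -0.14, Arr1 -0.56, Vha26 -0.51, RpS18 -0.13, RpL23 -0.39, RpS15 -0.18 and RpLP2 -0.20. On the spike-in scaling they were Vajk2 -1.12, vir-1 -0.50, cact -0.59, Diap2 -0.63, Hsp60A -0.86, Atg9 -0.68, Atg8b -0.68, Mst84Db -0.20, janB -0.77, Mst84Dd -0.41, Mst87F -0.56, Cp18 -0.41, Arr2 -0.53, Arr1 -1.19, Vha26 -1.14, RpS18 -0.76, RpL23 -1.02, RpS15 -0.81 and RpLP2 -0.84. At 48 h that scaling reversed vir-1 -0.74, Stam -0.22, cact -0.81, stv -0.0062, l(2)efl -0.15, Hsp68 -0.45, Ire1 -0.28, GstD2 -0.45, Atg8b -0.81, ImpL2 -0.38, Sp7 -0.31, dco -0.53, Pdp1 -0.58, Mlp84B -0.84, Act87E -0.87, Col4a1 -0.67, Mst57Da -0.69, SP -0.85, Acp95EF -0.76, Mst87F -0.74, Mst84Db -0.68, Mst84Dc -0.71, Mst84Da -0.78, trp -0.67, Arr2 -0.72 and RpL23 -1.0. The shift of all genes by -0.80 and -1.04 under that scaling is part of these values. Lists that turned downward, with the adjusted p in limma's camera, were ribosomal proteins as deposited at 24 h (0.010) and, on the spike-in scaling, heat shock (0.976), testis (0.817) and ribosomal proteins (0.0058) at 24 h and muscle (0.00051), accessory gland (0.0035), testis (0.247) and ribosomal proteins (0.0061) at 48 h. Directions also turned where neither value passed, for genes at 24 h with median centring Vajk2 -0.083, as deposited Vajk2 -0.48, on the spike-in scaling Diedel -0.086 and Tep3 -0.019, and at 48 h with the run block Diedel -0.52 and Tep4 0.060, on the spike-in scaling Diedel -0.64, Tep3 -0.22, p53 -0.36 and Vm34Ca -0.46. Lists did so at 24 h, with their adjusted p, as deposited autophagy 0.670 and eye and nerve 0.670, on the spike-in scaling small RNA 0.819, autophagy 0.576 and eye and nerve 0.490. At 48 h they were by fry apoptosis 0.968, melanization 0.891 and accessory gland 0.891, with the replicate block melanization 0.987, with the trimmed mean muscle 0.993 and accessory gland 0.239, as deposited autophagy 0.650, muscle 0.227, hemocyte 0.9998, accessory gland 0.057, female 0.784 and ribosomal 0.488, on the spike-in scaling autophagy 0.313, melanization 0.992 and female 0.088, with the run block apoptosis 0.918 and insulin and lipid 0.835, with the day block apoptosis 0.991. Without single arrays, such turns came within the ranges of Tep4 at 48 h (-0.069 to 0.047), Vajk2 at 24 h (-0.10 to 0.64), Diedel at 24 h (-0.19 to 0.57) and TotE at 48 h (-0.0041 to 0.88), and of the adjusted p of circadian at 24 h (0.607 to 0.972), female at 48 h (0.599 to 0.948), apoptosis at 48 h (0.896 to 0.979), accessory gland at 48 h (0.353 to 0.952), melanization at 48 h (0.896 to 0.994) and insulin and lipid at 48 h (0.640 to 0.952).

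The replicate letters share only a letter: the 18 same-letter pairs of arrays correlated at -0.12 to 0.07 in their deviations from the group means, none over 0.1, and 2 of 12 arrays correlated best with their own letter. With the letter as a replicate block the counts were 2293 at 24 h, 1205 at 48 h, 231 for the difference, 13 for Tris and 826 for DCV, with 11 and 10 lists. The block ended the call of the fat body list at 48 h (adjusted p = 0.052) and of 12 named-gene results, and changed no other call among the lists and named genes, while 2249 of the calls at 24 h and 1176 at 48 h were shared with the fit without it.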

Other observations

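The list tests within Tris were planned, and the remarks on single genes and on the second principal component were chosen only after the data were seen. Gene lists also shifted between 24 and 48 h after Tris alone. The changes are between Tris arrays, but the DCV arrays enter the estimate of the spread, and the lists were not tested on the Tris arrays by themselves. Antimicrobial peptide genes were lower at 48 h (median -0.22, adjusted p = 3.3e-05, and adjusted p = 0.018 with an estimated correlation), with 1 of 8 past the threshold, Def at -1.83 ± 0.27 (SE, n = 3 per group). Genes of the citrate cycle and respiratory chain were higher (median 0.15, adjusted p = 9.9e-08, and adjusted p = 0.0059 with an estimated correlation; 0 of 22 passed over all genes and 7 adjusted over the list alone). Accessory gland markers were higher too, under all 4 other scalings as well (median 0.31, adjusted p = 1.6e-08, and adjusted p = 0.049 with an estimated correlation; 0 of 13 passed over all genes and 6 adjusted over the list alone). Midgut markers were slightly higher (median 0.06, adjusted p = 6.9e-04, and adjusted p = 0.021 with an estimated correlation; 0 of 29 passed over all genes and 6 adjusted over the list alone), with a median of -0.03 and adjusted p = 0.092 as deposited. Lists called with the preset correlation alone were testis at -0.12 (adjusted p = 0.061 with an estimated correlation, and a median of 0.16 on the spike-in scaling), heat shock at -0.26 (adjusted p = 0.14 with an estimated correlation), circadian at -0.27 (adjusted p = 0.14 with an estimated correlation), detoxification at 0.12 (adjusted p = 0.11 with an estimated correlation) and glycolysis at 0.05 (adjusted p = 0.36 with an estimated correlation). The study's own list stood at -0.27 (adjusted p = 0.21 with an estimated correlation). None of the members of these 6 lists passed over all genes, and by fry detoxification alone of them passed (adjusted p = 0.024, against 0.10 to 0.31). By scaling, glycolysis lost its call with the trimmed mean, median centring and as deposited (adjusted p = 0.098 to 0.43), detoxification as deposited (adjusted p = 0.18), and testis, heat shock, circadian and the study's own list on the spike-in scaling (adjusted p = 0.82, 0.33, 0.061 and 0.33). Ribosomal protein genes passed downward with the trimmed mean, median centring and as deposited (adjusted p = 0.0048 to 0.011). The Tris arrays of 24 h all lay in 1 fluidics run that held no 48 h array, so time and run cannot be told apart here.

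The clock gene vri, a repressor, rose after DCV at both times, by 1.78 ± 0.23 and 1.76 ± 0.23, and by 2.08 with the run as a block at 48 h (adjusted p = 0.035), while tim fell at 24 h, at -0.89 ± 0.19. Array DCV replicate c of 24 h stood apart on the second principal component (10.2% of the variance), at 43.7 against -26.8 to 11.6 on the others.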
